A study of Homo sapiens with 3 samples.

How the data were processed

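The data were poly(A) RNA-seq libraries of the human bladder cancer cell line 5637 after siRNA transfection: 1 library of cells given a control siRNA (siNC) and 2 libraries of cells given siRNA against MYBL2 (siMYBL2-1 and siMYBL2-2). The labels do not say whether the endings -1 and -2 stand for different siRNA sequences or for repeats of 1 sequence. Both were therefore entered as 2 samples of 1 group, and the spread between them holds either kind of difference. Nothing in the labels says that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, total RNA was treated with DNase, poly(A) RNA was selected and fragmented, and the second cDNA strand was made with dUTP and removed, which keeps the strand of the RNA.

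Per the file headers, the authors deposited 1 table of RPKM values (reads per kilobase of exon, scaled to the assigned reads of the library), with the exon intervals and the exonic length of each of 35851 rows. cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d and the genome build hg38 are named in the submitters' processing notes, with no role or order. The read counter, its strand setting and the gene annotation are not given in the sources used here. The deposited RPKM multiplied by the deposited length was a whole multiple of 1 step per library for 100% of the values in each library, within a tolerance of 0.001 reads, so that the reads behind every value could be recovered. The assigned reads numbered 40259436 in siNC, 41818861 in siMYBL2-1 and 46177658 in siMYBL2-2. At these depths 3 reads on a transcript of 1 kilobase correspond to 0.0745, 0.0717 and 0.0650 RPKM. Intervals of ratios between 2 libraries are exact conditional binomial intervals at 95% confidence on the recovered reads. They cover counting error only, since reads without molecular identifiers are not independent molecules. RPKM is a share of all assigned reads, so a rise of some genes lowers the values of the others.

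Row names were matched to current gene symbols through a table of names and the RefSeq genes of GRCh38: 23245 rows carried a current symbol, 1139 an older symbol and 26 a name that a spreadsheet had turned into a date, which was resolved by position. Another 11440 names had no entry and 1 date-like name stayed unresolved. Of 24467 rows compared by name with GENCODE release 29, 24124 lay at an overlapping position, and biotypes were taken from that release. Coordinates are those of the deposited table, on hg38. Because no strand setting is given, each named gene was also given the share of its exonic bases that no other row covers on either strand. UPK3A, MS4A1, HBA1 and DCN, members of the gene lists, and MAL and TGM3, members of a list chosen later, were not analysed here.

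The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1) for the 13274 genes with a mean of at least 1 RPKM over the 3 libraries, with adjusted p-values by Benjamini-Hochberg and a threshold of 0.05. Log2 changes, log2 ratios and the folds of lists are on the log2(RPKM + 1) scale, which understates the change of low genes. Standard deviations over the 6353 genes of at least 5 RPKM, and their counting errors, instead use plain log2 ratios of RPKM. Folds of single genes and their counting intervals are plain ratios of the deposited RPKM. The fit has 1 residual degree of freedom, from the siMYBL2 pair, and 10.2 in total after moderation across genes. The single siNC library is assumed to vary like the siMYBL2 libraries. The test was tried on simulated data made from these libraries, with 200 of 13274 genes changed in each of 20 draws of siMYBL2 against siNC. It recovered 14.6% of the genes changed 2-fold, 95.7% of those changed 4-fold, 99.9% at 8-fold and 100% at 16-fold. Beside these it made 17.5 false calls per draw on average. That is more than a share of 0.05 of all its calls, so the adjusted p-values were too small in this simulation. All these shares hold only for 200 changed genes, because the Benjamini-Hochberg threshold loosens as more genes change. They do not give the power in the real data, where 1 gene passed. There MYBL2, at a mean log2 change of -2.03, did not pass (limma adjusted p 0.153). A rule of size that needs no spread counted genes with a log2 ratio to siNC of at least 1, or at most -1, in both siMYBL2 libraries. As both ratios share the siNC library, the overlap and the correlation were set beside 100 simulated draws of unchanged libraries with 1 shared control, whose noise was drawn from the differences of the siMYBL2 pair. The numbers of list members lower or higher in both libraries were set beside 400 draws made the same way, which were added after the data had been seen.

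Before the data were examined, 21 gene lists were fixed. For each list the median log2 ratio to siNC was taken in each siMYBL2 library and ranked among 10000 random lists of the same size, matched on mean expression. A list is said to stand apart where its percentile was under 2.5 or over 97.5 in both libraries. The percentile describes these libraries and is not a test across replicates. An adjusted p over a list alone corrects for the members of that list only, and not for the number of lists. The genes to name were also fixed beforehand: MYBL2 and CDCA3, the 10 genes with a symbol whose ratios were highest and the 10 whose ratios were lowest in both libraries (ranked by the ratio nearer 0), the 4 members with the largest mean ratio in the lists of G2/M and G1/S genes and 2 in every other list, all members of the CDCA list and of the MuvB, DREAM and MYB list, and the 3 genes at each end of the difference between both siMYBL2 libraries. A gene that this rule names is not reported here. A gene named outside this rule is said to have been chosen after its values were seen.

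The alternatives fixed beforehand were a pseudocount of 0.1 RPKM, no filter on low values, a filter at a mean of 5 RPKM, scaling by the median of ratios, quantile normalization, moderation without the trend or with robust hyperparameters, summing the rows of a name, a 1.5-fold rule, random lists without matching, and leaving out each siMYBL2 library. Protein-coding rows alone, removal of a smooth trend of the ratios on GC content and length, and limma-voom on the recovered reads were added after the data had been seen. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the rest.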

Results

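To find genes that lie downstream of MYBL2, a transcription factor of the MYB family that acts with the MuvB complex on late cell cycle genes, poly(A) RNA was sequenced from 5637 bladder cancer cells transfected with a control siRNA (siNC, 1 library) or with siRNA against MYBL2 (siMYBL2-1 and siMYBL2-2, 1 library each). Between 40259436 and 46177658 reads per library were assigned to genes, of which 91.8% to 92.4% lay in protein-coding genes. Mitochondrially encoded genes took 7.25% of the reads in siNC, 7.24% in siMYBL2-1 and 6.04% in siMYBL2-2, and the 10 most abundant genes took 8.85%, 8.71% and 8.24%. Over 6353 genes with a mean of at least 5 RPKM, the standard deviation of the log2 ratio was 0.483 between the siMYBL2 libraries, 0.553 between siNC and siMYBL2-1 and 0.357 between siNC and siMYBL2-2, against a median counting error of 0.0437 for the siMYBL2 pair. The siMYBL2-2 library thus lay closer to siNC than to siMYBL2-1. Over all 13274 genes tested, Pearson's correlation of its log2(RPKM + 1) values (0.981 with siNC, 0.968 with siMYBL2-1) had the same order.

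MYBL2 itself was lower in both siMYBL2 libraries. The gene (chromosome 20, 43667019 to 43716496, plus strand, hg38) was measured at 211 RPKM (23591 reads) in siNC, 46.0 RPKM (5340 reads) in siMYBL2-1 and 56.3 RPKM (7220 reads) in siMYBL2-2, a mean of 51.1 ± 7.30 RPKM (SD, n = 2) in the siMYBL2 group. The level was thus 21.8% of siNC in siMYBL2-1 and 26.7% in siMYBL2-2, or 4.59-fold lower (95% counting interval 4.45 to 4.73) and 3.75-fold lower (3.65 to 3.85). By limma the mean log2 change was -2.03 (SE 0.30), with an adjusted p of 0.153 over the 13274 genes tested, so the difference did not pass the threshold in this design of 2 libraries against 1. Its adjusted p was 0.0440 when only the 9927 protein-coding genes were tested and 0.00811 by limma-voom on the recovered reads, both added after the data had been seen, and it lay between 0.118 and 1.00 under the other settings.

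CDCA3, the gene that the title of the study places under the control of MYBL2, encodes a cell division cycle associated protein that takes part in entry into mitosis. It was expressed at a low level, 2.98 RPKM (679 reads) in siNC, 1.55 RPKM (367 reads) in siMYBL2-1 and 1.64 RPKM (427 reads) in siMYBL2-2, with a mean of 1.59 ± 0.0589 RPKM (SD, n = 2) in the siMYBL2 group. CDCA3 was 1.92-fold lower in siMYBL2-1 (95% counting interval 1.69 to 2.19) and 1.82-fold lower in siMYBL2-2 (1.61 to 2.06). The mean log2 change was -0.62 (SE 0.28) and limma gave an adjusted p of 0.999, so CDCA3 did not pass the threshold. CDCA3 lies on the minus strand of chromosome 12 (6844793 to 6852066), where its exons overlap those of GNB3 on the opposite strand, and 90.3% of its exonic bases belong to no other gene. GNB3, named here after its values were seen, was at 2.27, 1.29 and 1.06 RPKM in siNC, siMYBL2-1 and siMYBL2-2, and because no strand setting is given the reads of the shared bases cannot be assigned to either gene.

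**Figure D1:**
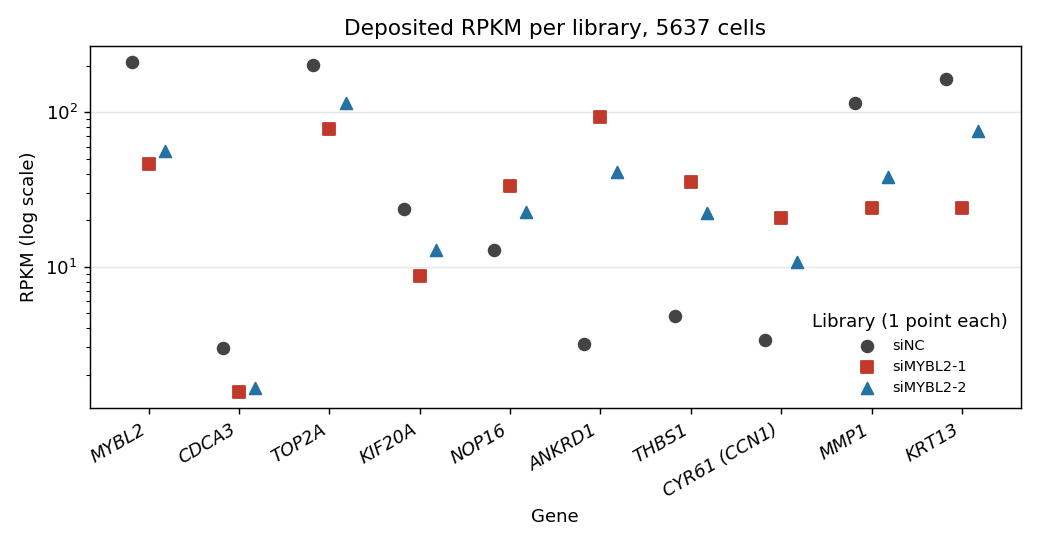
Deposited RPKM (log scale, vertical axis) of 10 genes (horizontal axis) in the siNC, siMYBL2-1 and siMYBL2-2 libraries, 1 point per library and no error bars. MYBL2 lies at 211 RPKM in siNC against 46.0 and 56.3 RPKM, CDCA3 at 2.98 against 1.55 and 1.64 RPKM, and ANKRD1 at 3.14 against 93.0 and 40.9 RPKM.

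Most other members of the CDCA family act in chromosome segregation or cell cycle transcription. Of the 7 genes of the list, 5 with CDCA3 included were lower in both siMYBL2 libraries, CDCA8 was higher in both and CDCA5 went in opposite directions. CDCA7L was at 25.9, 14.4 and 19.8 RPKM in siNC, siMYBL2-1 and siMYBL2-2, CDCA7 at 9.91, 6.83 and 6.75 RPKM, CDCA4 at 23.9, 19 and 18.3 RPKM, and CDCA2 at 11.9, 8.16 and 10.7 RPKM. CDCA8 was at 11.7, 12.6 and 14.8 RPKM and CDCA5 at 10.7, 9.27 and 11.5 RPKM. The median log2 ratio of the list was -0.48 in siMYBL2-1 and -0.37 in siMYBL2-2, at the percentiles 0.910 and 0.430 of random lists, so the list stood apart. In simulated unchanged libraries that share 1 control, 2.33 of the 7 genes (95% of draws 0 to 5) were lower in both, a range that holds the 5 observed. No member passed the limma threshold, over all genes or adjusted over the list alone (smallest adjusted p 0.273). The list was chosen around CDCA3, which the study had singled out, and with genes of at least 5 RPKM, a filter that removes CDCA3, its percentiles were 2.31 and 2.58 and it no longer stood apart.

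The list of G2/M and mitosis genes stood apart on the lower side, with the larger difference in siMYBL2-1. Of 55 measured genes, 41 were lower in both siMYBL2 libraries, 2 were higher in both and 12 went in opposite directions. Simulated unchanged libraries that share 1 control had 18.3 of them (95% of draws 12 to 26) lower in both. The median log2 ratio was -0.67 in siMYBL2-1 and -0.22 in siMYBL2-2, and each median lay below those of all 10000 random lists. TOP2A, the topoisomerase that untangles replicated chromosomes, was at 204 RPKM in siNC, 77.6 RPKM in siMYBL2-1 and 115 RPKM in siMYBL2-2, which is 0.381 (95% counting interval 0.375 to 0.387) and 0.566 (0.558 to 0.573) times siNC. KIF20A, a kinesin of cytokinesis, was at 23.6, 8.69 and 12.8 RPKM, the spindle protein gene NUSAP1 at 125, 51.9 and 75.6 RPKM, and CENPE, a kinetochore motor, at 30.7, 12 and 19.4 RPKM. The members higher in both libraries, named after their values were seen, were the mitotic kinase gene PLK1 (8.80, 10.6 and 12.8 RPKM) and CDC20, an activator of the anaphase-promoting complex (10.4, 10.8 and 14.5 RPKM). No member passed limma over all genes or adjusted over the list alone (smallest adjusted p 0.186), and 9 had an unadjusted p under 0.05.

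The siMYBL2 libraries themselves differed in these genes, with a median log2 ratio of siMYBL2-1 to siMYBL2-2 of -0.49 that lay below those of all random lists. This difference within the pair was larger than the mean of both medians against siNC (-0.44). Of the 20 lists with at least 3 measured members, 9 lay outside the central 95% of random lists in the ratio of siMYBL2-1 to siMYBL2-2, among them 3 of the 4 that stood apart from siNC. The simulated noise is independent between genes, so it does not cover a deviation of the single siNC library in a whole list, which would move both ratios the same way. The list of the G1/S transition and DNA replication stood apart by a smaller extent. Their median log2 ratio was -0.37 in siMYBL2-1 and -0.08 in siMYBL2-2 (percentiles 0 and 1.55), and 28 of 45 measured genes were lower in both libraries, 3 higher in both and 14 in opposite directions (simulated unchanged libraries, 14.9 lower in both, 95% of draws 9 to 21). MCM6, a subunit of the replicative helicase, was at 22.4, 9.66 and 16.2 RPKM in siNC, siMYBL2-1 and siMYBL2-2, TK1 (thymidine kinase) at 20, 9.01 and 18.9 RPKM, and POLD1 (DNA polymerase delta) at 24.3, 15.8 and 16.6 RPKM. CDC25A, a phosphatase that activates cyclin-dependent kinases, was higher, at 4.86, 9.56 and 6.75 RPKM. No member passed limma over all genes or adjusted over the list alone (smallest adjusted p 0.793), and against random lists not matched on expression the siMYBL2-2 median lay at the percentile 8.48, so the list then no longer stood apart.

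The list of MuvB, DREAM and MYB family genes did not stand apart. Over 14 genes of the MuvB complex, the DREAM complex and the MYB family, the median log2 ratio was -0.07 in siMYBL2-1 and 0.05 in siMYBL2-2 (percentiles 44.0 and 75.4), with 4 genes lower in both libraries, 6 higher in both and 4 in opposite directions. RBL2, a pocket protein of the DREAM complex, was at 3.32, 1.59 and 2.54 RPKM in siNC, siMYBL2-1 and siMYBL2-2, and E2F4 at 8.61, 13.0 and 11.6 RPKM. The related factor MYBL1 was at 3.44, 3.94 and 5.80 RPKM and MYB at 8.80, 7.26 and 8.99 RPKM. LIN9 and LIN54, subunits of MuvB, were at 2.84, 2.85 and 3.77 RPKM and at 2.5, 2.18 and 2.98 RPKM. No member passed limma over all genes or adjusted over the list alone (smallest adjusted p 0.915).

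The list of MYC and ribosome biogenesis genes stood apart on the higher side. Of 26 measured genes, 25 were higher in both siMYBL2 libraries (simulated unchanged libraries, 8.60, 95% of draws 4 to 13), and FBL, named after its values were seen, was lower in both (83.4, 73.0 and 71.3 RPKM in siNC, siMYBL2-1 and siMYBL2-2). The median log2 ratio was 0.74 in siMYBL2-1 and 0.40 in siMYBL2-2, 1.67-fold and 1.32-fold, and both medians lay above those of all 10000 random lists. The median log2 ratio of siMYBL2-1 to siMYBL2-2 was 0.32, also above all of them. NOP16, a nucleolar protein of large subunit assembly, was at 12.9, 33.3 and 22.6 RPKM, and NOLC1, a nucleolar phosphoprotein, at 81.4, 201 and 122 RPKM. MYC, chosen after its values were seen, was at 21.5, 43.3 and 24.5 RPKM. No member passed limma over all genes or adjusted over the list alone (smallest adjusted p 0.164), and 5 had an unadjusted p under 0.05. The cytosolic ribosomal protein genes did not stand apart, with medians of -0.01 and 0.07 over 31 genes (percentiles 58.3 and 64.6). In that list RPL27 was at 729, 553 and 537 RPKM and RPL18 at 9.48, 13.2 and 10.8 RPKM, and none of the 31 passed limma (smallest adjusted p over the list alone 0.996).

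**Figure D2:**
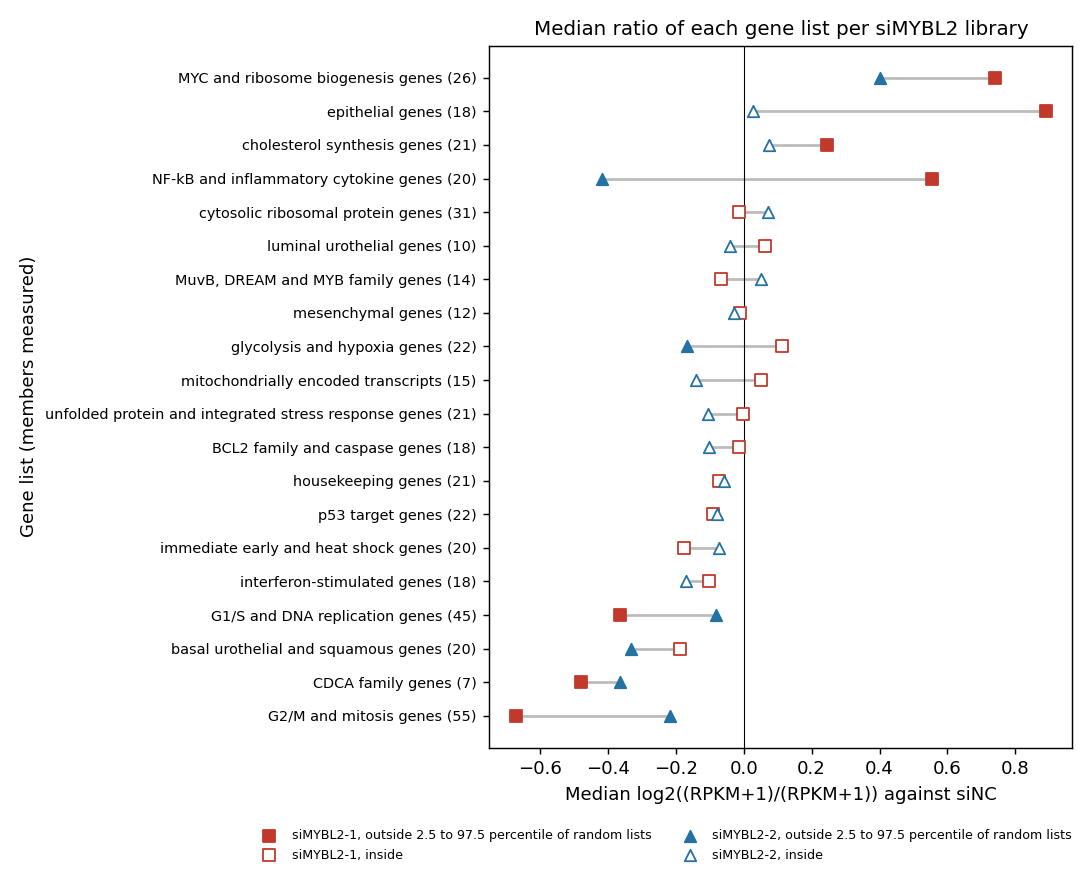
Median log2((RPKM+1)/(RPKM+1)) against siNC (horizontal axis) of each gene list with at least 3 measured members (vertical axis, number measured in brackets), with squares for siMYBL2-1 and triangles for siMYBL2-2, joined by a line; filled symbols lie outside the central 95% of random lists. Filled symbols on the same side of 0 in both libraries are seen for 4 lists, with medians of -0.67 and -0.22 for the G2/M genes and 0.74 and 0.40 for the MYC and ribosome biogenesis genes.

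Across all genes, limma called 1 gene higher and 0 lower in the siMYBL2 libraries, and 625 genes had an unadjusted p under 0.05. This number of unadjusted values is below a share of 0.05 of the 13274 genes tested, which would be expected if nothing had changed. The called gene was ANKRD1, which encodes an ankyrin repeat protein of muscle and is a known target of the TEAD transcription factors. ANKRD1 (chromosome 10, 90912096 to 90921276, minus strand) rose from 3.14 RPKM (250 reads) in siNC to 93.0 RPKM (7695 reads) in siMYBL2-1 and 40.9 RPKM (3736 reads) in siMYBL2-2, 29.6-fold (95% counting interval 26.1 to 33.7) and 13.0-fold (11.5 to 14.9), with a log2 change of 3.92 (SE 0.43) and an adjusted p of 0.0405. This call was lost, at an adjusted p between 0.153 and 1.00, without the filter on low values, with the filter at 5 RPKM, with either other scaling, with robust moderation and with the GC content and length trend removed. By limma-voom on the recovered reads 3 genes were higher and 7 rows lower. The higher genes were ANKRD1, THBS1 and AMOTL2, and the lower rows were MYBL2, MMP1, HEPHL1, WTAPP1, H19 and a further pair of short rows named after H19.

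The other genes that were highest in both siMYBL2 libraries were THBS1, FOSL1, CCN1, AMOTL2, SOX9, PHLDB2 and PROSER2. THBS1 (thrombospondin-1) was at 4.80, 35.3 and 22.4 RPKM in siNC, siMYBL2-1 and siMYBL2-2, a log2 change of 2.33 (SE 0.33, limma adjusted p 0.153). FOSL1, a subunit of the AP-1 transcription factor, was at 12.8, 78.6 and 40.9 RPKM, and CCN1 (CYR61 in the table), a secreted matricellular protein, at 3.34, 20.8 and 10.7 RPKM. AMOTL2, an angiomotin family protein, was at 5.36, 24.6 and 17.6 RPKM, and the transcription factor SOX9 at 2.82, 10.9 and 9.76 RPKM. PHLDB2 was at 6.2, 17.9 and 16.2 RPKM and PROSER2 at 2.13, 12.6 and 6.18 RPKM. The adjusted p of these 6 genes lay between 0.228 and 0.421. MIR3176 and MIR6720, the other rows that the rule names, had at most 10 reads in a library and support no statement on level.

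Among the genes lowest in both siMYBL2 libraries after MYBL2 were MMP1, H19, HEPHL1 and AQP3. MMP1, the interstitial collagenase, was at 116 RPKM in siNC, 24.0 RPKM in siMYBL2-1 and 38.2 RPKM in siMYBL2-2, 0.208 (95% counting interval 0.198 to 0.218) and 0.331 (0.318 to 0.344) times siNC. WTAPP1, a transcribed pseudogene whose span on the opposite strand holds MMP1, was at 55.4, 10.9 and 16.8 RPKM, and 92.0% of its exonic bases and 92.4% of those of MMP1 belong to no other gene. The imprinted long noncoding RNA H19 was at 235, 43.3 and 79.1 RPKM, HEPHL1, a ferroxidase-like protein, at 7.64, 1.66 and 1.93 RPKM, and the water and glycerol channel AQP3 at 30.0, 7.00 and 11.2 RPKM. The limma adjusted p of these 5 genes lay between 0.218 and 0.308. The small or pseudogene rows HMGN2P4, RNU6ATAC18P, MIR6783 and MIR6080 were named by the same rule on at most 178, 24, 14 and 11 reads in a library.

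By size alone, 28 genes were at least 2-fold higher and 54 at least 2-fold lower in both siMYBL2 libraries, and 0 were 2-fold different in opposite directions. In siMYBL2-1 alone 286 genes were 2-fold higher and 237 lower, and in siMYBL2-2 alone 56 were higher and 121 lower. Independent lists of those sizes would share 1.21 and 2.16 genes. Unchanged libraries that share 1 control and are as noisy as the siMYBL2 pair shared 48.8 (95% of draws 37.0 to 60.5) higher and 47.1 (32.5 to 60.0) lower genes in simulation, so the observed overlap lay below and within these ranges. These ranges may be too high. Over the 13274 genes tested, the log2 ratio within the siMYBL2 pair had a standard deviation of 0.422, against 0.328 for siMYBL2-2 to siNC. The simulated noise may also hold a real difference between the siMYBL2 libraries. Pearson's correlation of both log2 ratios across genes was 0.495 against 0.5 in simulation, Spearman's was 0.457 against 0.476, the share of genes with the same sign was 66.1% against 66.5%, and the covariance was 0.0769 against 0.0890, a difference of -0.0121. Genes are not independent replicates, and with 1 siNC library the control could not be split. Part or all of the overlap may come from the shared control, and these values do not show how much.

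**Figure D3:**
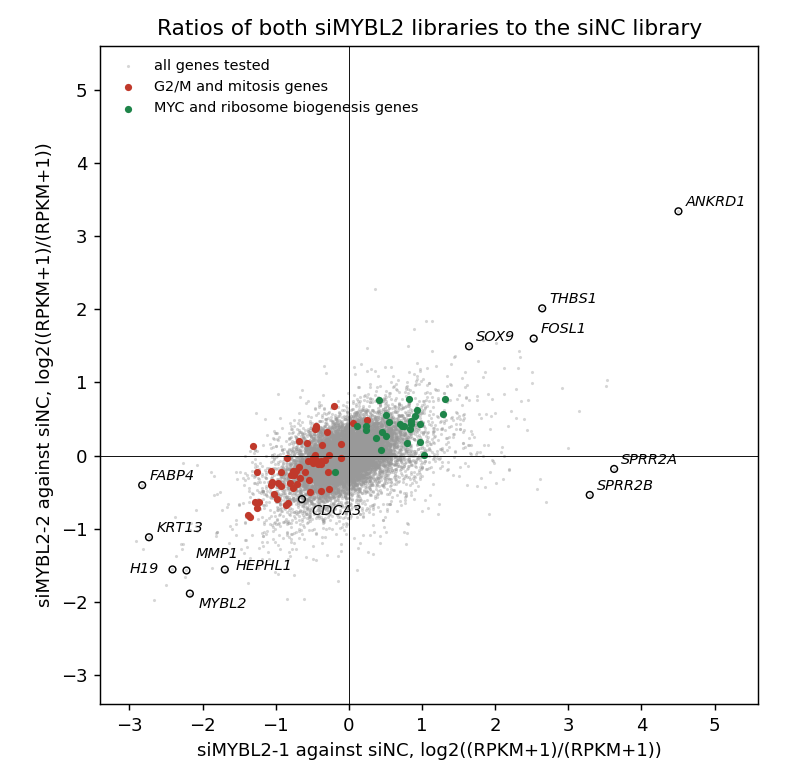
Log2((RPKM+1)/(RPKM+1)) against siNC in siMYBL2-1 (horizontal axis) and in siMYBL2-2 (vertical axis), 1 point per gene for the 13274 genes tested, with the G2/M and mitosis genes in red, the MYC and ribosome biogenesis genes in green and selected genes circled. MYBL2 lies at -2.17 and -1.89, CDCA3 at -0.64 and -0.60 and ANKRD1 at 4.51 and 3.34, while SPRR2A (3.63 and -0.18) and FABP4 (-2.83 and -0.40) differ between both libraries.

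The siMYBL2 libraries went apart in genes of inflammation. Over 20 measured NF-kB and cytokine genes the median log2 ratio to siNC was 0.55 in siMYBL2-1 and -0.42 in siMYBL2-2, above and below those of all random lists, and 15 genes went in opposite directions. CXCL1 and CSF2, chosen after their values were seen, were at 33.0, 104 and 29.7 RPKM and at 1.80, 9.21 and 1.07 RPKM in siNC, siMYBL2-1 and siMYBL2-2. CSF3 (3.43, 1.48 and 1.13 RPKM) and TNFAIP2 (168, 86.3 and 87.9 RPKM), the members with the largest mean ratio, were lower in both. The epithelial genes had a median of 0.89 in siMYBL2-1 (percentile 100) and of 0.03 in siMYBL2-2 (percentile 57.2), with the tight junction genes CLDN1 at 6.84, 29 and 9.10 RPKM and CLDN4 at 4.26, 21.3 and 4.46 RPKM. The 3 genes most in excess in siMYBL2-1 over siMYBL2-2 were the cornified envelope genes SPRR2A (85.2, 1064 and 75 RPKM), SPRR2B (12.1, 127 and 8.00 RPKM) and SPRR2E (1.9, 17.7 and 0.856 RPKM), near-identical copies at 1 locus whose reads may be split between them. Those most in deficit were the fatty acid binding protein gene FABP4 (79.6, 10.4 and 59.9 RPKM), HMGN5 (39.6, 7.44 and 36.8 RPKM) and the protease inhibitor gene SPINK5 (12.7, 2.26 and 11.6 RPKM). None of these 12 genes passed limma for siMYBL2 against siNC, and none of the members of both lists did so adjusted over the list alone (smallest adjusted p 0.0830 and 0.248).

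Basal and luminal urothelial genes did not stand apart as lists. The 20 basal and squamous genes had medians of -0.19 in siMYBL2-1 (percentile 7.81) and -0.33 in siMYBL2-2 (percentile 0), with COL17A1, a hemidesmosome collagen, at 41.1, 15.4 and 29.9 RPKM in siNC, siMYBL2-1 and siMYBL2-2 and SPRR1B at 21.2, 69.7 and 23.5 RPKM. With genes of at least 5 RPKM this list stood apart, at the percentiles 1.22 and 0.01. The 10 luminal genes had medians of 0.06 and -0.04 (percentiles 73.8 and 35.1). Among them the keratin gene KRT13 was at 165, 24.0 and 75.7 RPKM, with an adjusted p of 0.582 over all genes and 0.0421 adjusted over the list alone, and GRHL3 was at 0.712, 8.03 and 1.42 RPKM. The 12 mesenchymal genes had medians of -0.01 and -0.03 (percentiles 64.4 and 41.7), with VIM at 0.453, 1.20 and 2.09 RPKM and the gelatinase gene MMP2 at 7.41, 3.75 and 4.57 RPKM. No basal or mesenchymal gene passed limma over all genes or adjusted over the list alone (smallest adjusted p 0.207 and 0.206).

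Of the stress and survival lists, none stood apart. The 22 p53 target genes had medians of -0.09 and -0.08 in siMYBL2-1 and siMYBL2-2 (percentiles 37.1 and 16.6), with PLK2 at 16.6, 51.9 and 32.6 RPKM in siNC, siMYBL2-1 and siMYBL2-2 and PLK3 at 1.57, 6.99 and 2.04 RPKM, and none of them passed limma, over all genes or adjusted over the list alone (smallest adjusted p 0.0836). In the 18 genes of the BCL2 family and caspases (medians -0.01 and -0.10, percentiles 57.4 and 11), BMF, a pro-apoptotic member, was at 4.55, 1.45 and 1.58 RPKM, with a limma adjusted p of 0.459 over all genes and 0.0388 adjusted over the list alone. The anti-apoptotic BCL2L1 was at 12.2, 36.6 and 18.2 RPKM. The immediate early and heat shock genes had medians of -0.18 and -0.07 (percentiles 6.97 and 8.86), with 11 of 20 genes lower in both libraries and 7 higher in both. Adjusted over the list alone, 3 of them passed limma, against 0 over all genes: FOSL1 was higher, while EGR1 (46.3, 12.6 and 21.8 RPKM) and FOS (8.33, 1.68 and 3.53 RPKM), the latter chosen after its values were seen, were lower. The 21 unfolded protein and integrated stress response genes had medians of 0.00 and -0.11 (percentiles 67.0 and 5.35), with DDIT4 at 46.5, 32.9 and 30.4 RPKM and CALR at 591, 402 and 433 RPKM, and again none passed (smallest adjusted p over the list alone 0.993). Other genes cover part of BCL2L1 and DDIT4, of whose exonic bases 57.0% and 58.8% are their own, so their values are uncertain.

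The remaining lists did not stand apart either. The 21 cholesterol synthesis genes had medians of 0.25 (percentile 99.7) in siMYBL2-1 and 0.07 (percentile 90) in siMYBL2-2, and CYP51A1 was at 7.00, 10.7 and 8.05 RPKM in siNC, siMYBL2-1 and siMYBL2-2, with 17.8% of the exonic bases of CYP51A1 free of other genes. The 22 glycolysis and hypoxia genes had medians of 0.11 (percentile 91.5) and -0.17 (percentile 0.970), with NDRG1 at 4.56, 1.99 and 1.97 RPKM and HK2 at 3.30, 8.52 and 4.43 RPKM. The 18 interferon-stimulated genes had medians of -0.10 and -0.17 (percentiles 30.6 and 2.69), with IFI44 at 11.5, 3.57 and 9.04 RPKM and EPSTI1 at 4.26, 7.89 and 6.53 RPKM. The 15 mitochondrially encoded transcripts had medians of 0.05 and -0.14 (percentiles 68.7 and 4.28), where MT-CO3 had log2 ratios of -0.40 and -0.52 and MT-ND3 of -0.03 and -0.49. The 21 housekeeping genes had medians of -0.07 and -0.06 (percentiles 30.1 and 9.82), although ACTB was at 327, 577 and 533 RPKM and CHMP2A at 64.9, 34.6 and 47.9 RPKM. Of 26 markers of leukocytes, endothelium and fibroblasts 1 reached a mean of 1 RPKM, CD68 at 3.43, 5.34 and 4.0 RPKM, and 14.2% of its exonic bases belong to no other gene. No member of these 6 lists passed limma, and none of the first 5 had a member below 0.202 adjusted over the list alone.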

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

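Protein-coding rows alone, removal of the GC content and length trend and limma-voom on recovered reads were chosen after seeing the data. The direction of MYBL2 (log2 change -2.03, from -2.06 to -1.99 over the tested alternatives, and from -2.17 to -1.89 with 1 siMYBL2 library left out) and of CDCA3 (-0.62, from -0.90 to -0.57, and from -0.64 to -0.60 with 1 library left out) held throughout, as did the sign of both medians of the 4 lists that stood apart. Among the other lists 14 medians in 8 lists changed sign, from at most 0.10 to at most 0.12 in size: the mesenchymal median in siMYBL2-2, for example, went from -0.03 to 0.07 with the trend removed. MYBL2 passed the limma threshold among protein-coding rows (-2.03, adjusted p 0.0440) and by limma-voom (-2.05, adjusted p 0.00811), and its adjusted p lay between 0.118 and 1.00 otherwise. Among protein-coding rows fewer genes were tested, and the moderation was fitted anew, with prior degrees of freedom of 11.3 against 9.16. The share of each in the lower adjusted p was not tested. CDCA3 passed under none of the settings, with adjusted p between 0.670 and 1.00, and the filter at 5 RPKM removes it. The limma count of higher genes was 1, and it was 0 without the filter on low values, 0 with the filter at 5 RPKM, 0 with median-of-ratios scaling, 0 with quantile normalization, 0 with robust hyperparameters, 0 with the GC content and length trend removed, 2 among protein-coding rows and 3 by limma-voom. The count of lower genes was 0, and 1 among protein-coding rows and 7 by limma-voom. Without the filter 2364 genes had an unadjusted p under 0.05.

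Genes 2-fold higher and lower in both siMYBL2 libraries numbered 28 and 54, but 93 and 107 with a pseudocount of 0.1 RPKM, 18 and 28 with the filter at 5 RPKM, 16 and 24 among protein-coding rows and 175 and 268 by the 1.5-fold rule. With 1 library left out they ranged from 56 to 286 higher and from 121 to 237 lower. The correlation of both ratios was 0.495, and 0.479 with the pseudocount of 0.1 RPKM, 0.513 with the filter at 5 RPKM and 0.529 with the GC content and length trend removed. Of the gene lists 4 stood apart, and 7 by either siMYBL2 library alone. The G2/M median, averaged over both libraries, was -0.44 (from -0.67 to -0.22 with 1 library left out) and the G1/S median -0.22 (from -0.37 to -0.08). Except where stated, the cause of these shifts was not tested. Leaving out a siMYBL2 library leaves no residual degree of freedom, so it gives values and no test. The edgeR quasi-likelihood test, planned only for a table that holds raw counts, was not run, and limma-voom was run on the recovered reads instead. No paired analysis was possible because the control has 1 library and the groups share fewer than 2 replicate numbers. Depth limits the short rows named with at most 24 reads in a library.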

Other observations

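The lists in this part were chosen after the highest and lowest ratios had been seen, and leave out the genes seen by then. The single genes named from them in this part were chosen after their values were seen. Their predictions were written before their own values were seen, whereas the tests of a deviation of siNC, of an effect in 1 siMYBL2 library and of the trend in the unseen TEAD targets, and the simulated counts, were chosen after the results were known. A list of known targets of the TEAD transcription factors, which work with the coactivators YAP and TAZ, stood apart on the higher side. Of 14 measured targets 11 were higher in both libraries (4.69 in simulated unchanged libraries that share 1 control, 95% of draws 1 to 8), 2 were lower in both and 1 went in opposite directions. The median log2 ratio was 0.76 in siMYBL2-1 and 0.45 in siMYBL2-2, and the siMYBL2 libraries differed from each other in this list, with a median log2 ratio of siMYBL2-1 to siMYBL2-2 of 0.36 (percentile 99.97). FJX1 was at 1.82, 11.3 and 4.06 RPKM in siNC, siMYBL2-1 and siMYBL2-2, LATS2, a kinase of the Hippo pathway, at 0.980, 2.87 and 1.91 RPKM, TGFB2 at 2.00, 3.47 and 5.02 RPKM and CCN2 (CTGF in the table) at 1.06, 1.78 and 2.98 RPKM, while IGFBP3 was lower, at 67.0, 43.3 and 33.6 RPKM. The list of actin cytoskeleton and SRF target genes also stood apart on the higher side, with medians of 0.47 and 0.36 and a median ratio within the pair of 0.03 (percentile 74.9). Of its 18 measured genes 15 were higher in both libraries (5.93 in simulation, 2 to 10), 1 was lower in both and 2 went in opposite directions. Among those higher were CNN3 at 19.6, 49.8 and 36.1 RPKM, VCL (vinculin) at 6.64, 12.5 and 10.2 RPKM and FLNA (filamin A) at 33.8, 52.4 and 54.7 RPKM. No member of either list passed limma over all genes or adjusted over the list alone (smallest adjusted p 0.0819 and 0.108). GADD45A of the TEAD list is also in the p53 list, and TAGLN of the actin list is also in the mesenchymal list. The simulated noise is independent between genes here too, so it does not cover a deviation of siNC in a whole list.

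A hypothesis is that TEAD activity, and SRF activity at actin cytoskeleton genes, was higher in these siMYBL2 cultures than in the siNC culture. It does not extend to the immediate early genes. Of these, EGR1 and FOS were lower in both siMYBL2 libraries and FOSL1 was higher in both. The list of immediate early and heat shock genes did not stand apart (percentiles 6.97 and 8.86). The smaller of both percentiles was 100 for the TEAD list and 100 for the actin and SRF list, so no random list had a median as high in either library. The tables argue against a trend of the ratios on GC content or length as the whole cause. With the trend removed, the medians of the 14 unseen targets were 0.74 and 0.47, at least 97.4% of their values before, and lay above those of all random lists in both libraries. The 6 targets already seen kept 99.995% of their median, but they were picked for being highest and decide nothing. A deviation of the single siNC culture, such as a denser plating, cannot be told apart from an effect of the siRNA, because the design has 1 siNC library. Counts with 1 library set alone cannot decide this, because each takes its spread from the other pair. If nothing had changed, a share of 0.05 of the 13274 genes tested would be expected. With siNC set against the other libraries 625 genes had an unadjusted p under 0.05 by limma, against 2023 for siMYBL2-1 and 177 for siMYBL2-2.

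The siMYBL2-1 library was the one that differed most from the other pair. With siMYBL2-1 set alone limma called 71 genes, 62 higher and 9 lower in it, against 1 with siNC alone and 0 with siMYBL2-2 alone (177 at an unadjusted p under 0.05). This contrast takes its spread from siNC and siMYBL2-2, which were treated differently and were the closest pair, and the order of the counts follows the standard deviations of the pairs (0.357, 0.483 and 0.553). Chosen after their values were seen, PLAUR, EDN1, IL1RN, SERPINB2 and KRT81 were among the higher genes and HMMR and PIR among the lower. The median difference of the called genes was 29.7 counting standard errors, but these genes were chosen by the call. Over the 6353 genes of at least 5 RPKM, the log2 ratio of the siMYBL2 pair had a standard deviation of 0.483. The median counting error was 0.0437. Between siNC and siMYBL2-1 these values were 0.553 and 0.0452. They argue against counting error as the whole cause of the differences in those genes, and do not tell other causes apart. GC content and length explained 5.62% of the variance over genes of this contrast, although with that trend removed 3 calls were left, all SPRR2 genes: the median size of the difference went from 1.82 to 1.78, while the prior degrees of freedom went from 6.59 to 4.94, which makes the test stricter. Whether the stricter test is why fewer calls were left was not tested. An effect of that transfection which siMYBL2-2 does not share, whether from a different siRNA sequence or from handling, may account for the 71 calls and cannot be told apart from other causes with 1 library.

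A list of suprabasal squamous genes, set up because KRT13 and similar genes were among the lowest, did not stand apart. Its median log2 ratio was 0.10 in siMYBL2-1 (percentile 87.2) and -0.36 in siMYBL2-2 (percentile 0.160), so a decrease of the list shared by both libraries is neither shown nor excluded. The ratio of siMYBL2-1 to siMYBL2-2 had a median of 0.24 (percentile 97.7, and 97.1 with the GC content and length trend removed). Of 11 measured genes 5 were lower in both libraries (3.65 in simulation, 1 to 7), 2 were higher in both and 4 went in opposite directions. The 5 were S100A7 (29.5, 9.50 and 15.6 RPKM in siNC, siMYBL2-1 and siMYBL2-2), SLPI (103, 46.5 and 66.1 RPKM), KRT4, LYPD3 and S100P. No member passed limma over all genes or adjusted over the list alone (smallest adjusted p 0.0541).

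Rows at 1 locus sometimes moved together, as MMP1 and WTAPP1 did. Reads counted in every row they overlap, on either strand, are a candidate explanation. Over 46 rows whose exons lie wholly inside those of an opposite-strand row of at least 20 RPKM, the median ratio of their RPKM to that of the other row was 0.333. Over 14 rows contained in the same way in a row on the same strand, where such counting would act whatever the strand setting, it was 0.0529. Rows with no exonic base of their own nevertheless held reads: 554 of 573 rows covered on the same strand (96.7%) and 407 of 436 covered only with the help of opposite-strand rows (93.3%), against 82.2% of the 22443 rows without exonic overlap. Reads on shared bases were thus not simply left out, but these counts do not show whether a read was given to every row or to 1 of them, and neither median gives a yardstick. The explanation and the strand setting stay open. MMP1 and WTAPP1 share few of their exonic bases, and no biological explanation was tested for this pattern.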
